A study of Mus musculus with 4 samples.

How the data were processed

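RNA abundance was measured by sequencing in whole testes of mice at postnatal day 18. The series holds 4 libraries, 2 from wild-type mice and 2 from mice in which Sympk was conditionally knocked out (cKO) with Stra8-Cre, a recombinase expressed in male germ cells before meiosis. The mice were on a mixed C57BL/6 and ICR background. Per the labels' protocols, total RNA was turned into paired-end libraries with a TruSeq RNA kit, using fragmented mRNA and random primers. The protocol text names neither a strand-marking step nor the number of animals behind a library. No label says that the libraries come from separate animals, so the p-values measure only the spread between these samples, which may be technical.

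Reads were aligned with HISAT2 to GRCm38, per the submitters' processing notes, which give no version. The counting program, its strand setting and the gene annotation are not given in the sources used here. The authors deposited a table of read counts per gene, whole numbers with no normalization, for 53465 genes. Beside the counts, the authors deposited FPKM values (fragments scaled to gene length and library total). Every one of the 12705 genes with over 100 counts in every library had one gene length behind its count and FPKM in all 4 libraries, within 0.01%, so the FPKM values hold the same counts divided by the library total and a fixed length. The median of these lengths was 6094 bp. The FPKM columns were used for this check only. No row lacked a gene name, and no column of sample values was left unused.

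Gene IDs were matched to the GENCODE M21 annotation of GRCm38. Of the IDs in the table, 53360 matched, 99.9% of them on the same chromosome and 96.3% with the same start and end. Coordinates are those of the deposited table. Library totals ran from 32730868 to 41584389 counts, so that 1 CPM (1 count in every 1000000) corresponded to 32.7 to 41.6 counts. Counts of 0 were given a floor of 3 counts per library, which is 0.072 to 0.092 CPM. Folds against a gene at 0 in a whole group are lower bounds set by that floor. Ratios with 1 to 3 counts in a group are given with exact 95% counting intervals. Floors and intervals cover counting error only.

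The 2 replicates of each group were compared first. The chi-square statistic per gene was 51.1 between the wild-type libraries and 24.2 between the cKO libraries, far above sampling noise, so all 4 libraries were kept as separate samples. Genes were filtered with edgeR's filterByExpr and libraries were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3). The test was edgeR's quasi-likelihood test of genotype with no other term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Of the genes in the table, 21822 were tested. Levels are given as TMM-scaled CPM, as the mean ± SD of 2 libraries, and fold changes as log2 of cKO over wild type with their standard error (SE).

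Before the data were examined, the groups, the test, the alternatives, the rule for naming genes and 26 gene lists were fixed. The lists cover germ cell stages, somatic cell types of the testis, blood and duct contaminants, meiotic processes, RNA 3' end processing, histones, splicing, tight junctions, p53 targets, the mitotic cell cycle, stress, mitochondrial and ribosomal genes. They hold 523 distinct tested genes, 16 of them in more than 1 list. Each list was tested with limma's camera (limma 3.58.1) on log2 CPM with a preset correlation between genes of 0.01, adjusted over the 26 lists, then with an estimated correlation, and with fry, which asks whether a list moved on balance one way without setting it against other genes. The naming rule took Sympk, the 12 named genes with the largest rise and the 12 with the largest fall among changed genes with a mean of at least 5 CPM, leaving out clone and predicted symbols. From each list it took up to 3 changed members with the largest change in the main direction and up to 1 in the other. Genes outside the rule are said to be chosen after their values were seen. A gene that the rule names is not reported here.

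The alternatives were a replicate block, DESeq2 1.42.0, limma-voom, RLE size factors, library totals alone, no filter on low counts, a mean of at least 5 CPM, and each library left out in turn. Where a library was left out, the group with 1 library was assumed to vary like the other. Scaling to the Sertoli cell list, leaving out the muscle, stress and mitochondrial genes, and 7 further gene lists were chosen after seeing the data. Shuffling and bootstrap tests were run in Python 3.11.15 with scipy 1.17.1.

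The procedure was tested on simulated data: in 5 simulations of cKO against wild type with 20830 genes tested, 200 of them changed, it recovered 42.4% of the genes changed 2-fold and 96% of those changed 4-fold, with 5.1% false calls. A shifted list was found in 5 of 5 simulations, and 0 of 125 unshifted lists were called. The simulated genes varied independently, and few of them changed, up or down at random, whereas 63.4% of tested genes changed in the data. The simulations therefore do not measure power, scaling bias or false list calls under the conditions of these data.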

Results

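Gene expression was compared between whole testes of wild-type mice and of mice lacking Sympk in germ cells (Sympk cKO), with 2 libraries per group, all from postnatal day 18. At this age the testis holds spermatogonia, spermatocytes of the first meiotic wave and the somatic cells around them. Sympk encodes symplekin, a scaffold of the complex that cleaves and polyadenylates mRNA 3' ends. The series set out to ask how transcript levels differ between the genotypes in a study of Sympk and meiosis. The wild-type libraries held 41584389 and 37764044 counts and the cKO libraries 40994172 and 32730868 counts. Mitochondrially encoded genes took 4.93% and 4.01% of the counts in the wild-type libraries and 10.19% and 8.81% in the cKO libraries.

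Whole-testis Sympk RNA was present in every library. It was lower in the cKO libraries by an amount that the test did not tell from the spread between libraries. The gene (ENSMUSG00000023118) lies on the plus strand of chromosome 7 from 19024377 to 19054618 (GRCm38). Its level was 225.2 and 192.0 CPM in the wild-type libraries and 171.5 and 173.2 CPM in the cKO libraries, a mean of 208.6 ± 23.5 against 172.4 ± 1.23 CPM (SD, n = 2). The log2 fold change of -0.28 (SE 0.141) did not pass the threshold (adjusted p = 0.132, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Without wild-type replicate 2 the value was -0.41 and passed it (adjusted p = 0.0313), and without any other single library it did not. Counts over a whole gene do not separate the deleted exons from the rest, and Stra8-Cre acts in germ cells alone, so this comparison is a weak check of the labels.

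The cKO testes differed from wild type in most of the transcriptome. Most listed genes of meiosis and of later germ cells fell, many to near 0. Most listed markers of somatic cells and spermatogonia were higher on the scale used: 22 of 24 for Sertoli, 12 of 17 for Leydig, 9 of 12 for peritubular, 14 of 14 for endothelial and 16 of 19 for macrophage cells, and 15 of 22 for spermatogonia, with list medians from 0.88 to 1.28 on the log2 scale. Id4, Sohlh2, Ptgds and Fcgr3 among them fell, though the Ptgds call was lost under several alternatives. None of these lists, rising or falling, passed camera with an estimated correlation between genes (adjusted p = 0.374 for each). With 2 libraries per group that correlation is estimated from few samples, so a list without a call there may still differ from other genes. The piRNA gene Piwil1 went from 1422 ± 174 CPM to 12.6 ± 1.97 CPM, and the sperm-type glycolytic enzyme gene Pgk2 from 63.2 ± 6.16 to 0.115 ± 0.0308 CPM. Amh, the anti-Müllerian hormone gene of Sertoli cells, went from 19.2 ± 0.716 to 64.9 ± 12.5 CPM (SD, n = 2 for each).

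Of the 21822 genes tested, 13845 changed (63.4%), 6368 higher and 7477 lower in the cKO testes. At least 2-fold changes were found in 10003 genes, 4256 higher and 5747 lower. Large falls outnumbered large rises: 2015 genes were at least 16-fold lower and 38 at least 16-fold higher by fitted fold change. For genes at 0 counts in a group the fitted value can exceed the bound. Tex13a, with a fitted log2 fold change of -7.16, was bounded at 6.1-fold, so not all of these genes are shown to differ 16-fold. Of the lower genes, 638 had 0 counts in both cKO libraries, while 15 of the higher genes had 0 counts in both wild-type libraries. The first principal component held 93.1% of the variance and parted the genotypes. Correlations of log2 CPM across genes were 0.98 between the wild-type libraries, 0.988 between the cKO libraries and 0.788 to 0.807 across genotypes. Genes are not independent replicates, and the split of calls depended on the scaling. Library totals alone gave 7651 higher and 6423 lower genes, with the median of all genes moved from -0.02 to 0.20 on the log2 scale. Scaling to the fixed list of Sertoli genes, an alternative chosen after seeing the data, gave 392 higher and 13524 lower genes and a median of -1.22. Every rise named here is relative to the TMM scale, and only rises larger than that of the Sertoli list stay above 0 on the Sertoli scale.

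**Figure D1:**
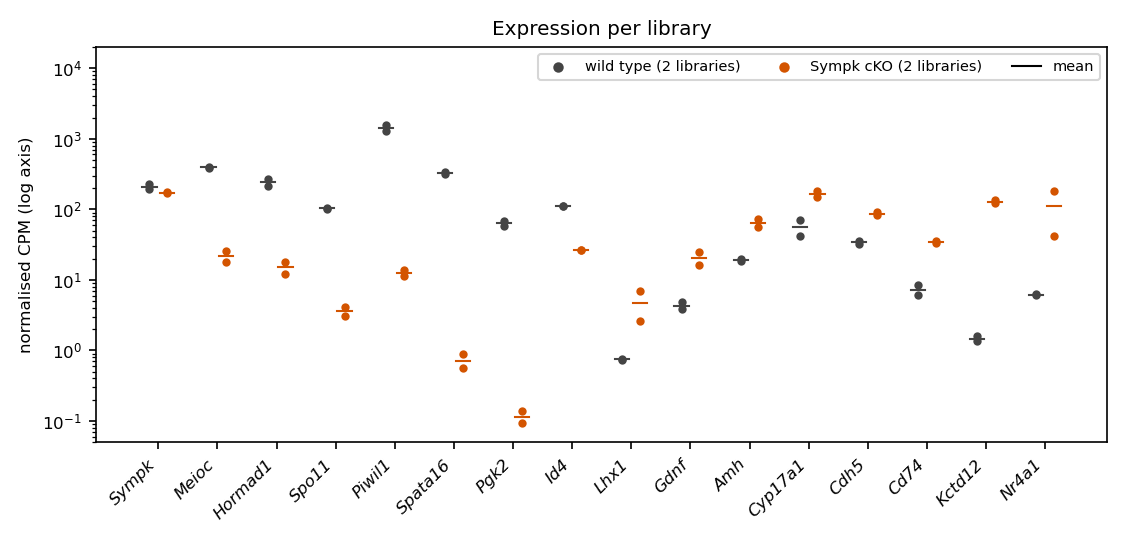
Expression of 16 named genes in each library, in TMM-scaled CPM on a log axis, with points for the 2 wild-type (grey) and 2 Sympk cKO (orange) libraries and a line at each mean. Pgk2 and Spata16 lay under 1 CPM in both cKO libraries, Sympk lay between 171.5 and 225.2 CPM in all 4 libraries, and Amh, Cdh5, Cd74 and Kctd12 were higher in both cKO libraries on this scale.

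The deepest falls reached 0 or a few counts in both cKO libraries together. Ccdc178 (chromosome 18, 21810897 to 22171396) went from 98.6 ± 10.9 CPM to 0 counts in both cKO libraries, at least 1294.5-fold lower (adjusted p = 1.51e-05). Prss39, a testis serine protease gene on chromosome 1 (34498410 to 34503063), went from 63.9 ± 8.15 CPM to 0 and was at least 839.6-fold lower. Bpi, Prss21, Prss47, Atp6ap1l and Tsga10ip also had 0 counts in both cKO libraries, with lower bounds of 350.3-fold, 320.4-fold, 186.7-fold, 148.9-fold and 134.9-fold. Speer1 kept 1 count in the cKO libraries against 2246 in wild type, a ratio of 2427.4 with an exact 95% interval of 435.2 to 95921.2. Tex22 and Pou5f2 each kept 2 counts, with ratios of 2115.1 (585.1 to 17471.2) and 1862.2 (515.1 to 15382.9), and Ccdc7b kept 3, with a ratio of 1693.6 (579.2 to 8215.3). AY702103 fell from 108.4 ± 16.7 to 0.0508 ± 0.00570 CPM. Speer1 and Ccdc7b have near-identical copies in the genome, so their counts depend on how shared reads were assigned.

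The largest rises were fewer and of mixed kinds. Kctd12, which encodes an auxiliary subunit of GABA-B receptors, rose on chromosome 14 (102976581 to 102982637) from 1.48 ± 0.143 to 128.5 ± 10.6 CPM (log2 fold change 6.44, SE 0.186, adjusted p = 1.2e-05). Kndc1 rose from 7.52 ± 0.842 to 85.2 ± 8.86 CPM, with a log2 fold change of 3.50 (SE 0.175), and Clmn, which encodes calmin, from 1.21 ± 0.401 to 10.9 ± 0.674 CPM. Frrs1 rose by 3.52 (SE 0.345) and Wipf1, an actin regulator gene, by 3.05 (SE 0.361). Without wild-type replicate 1 the Wipf1 value was 3.69. Pet117 had 2 counts in wild type and 819 in the cKO libraries, a ratio of 378.9 (exact 95% interval 104.6 to 3133.9), and it overlaps Kat14, so reads of either gene may have been counted for the other. The fast muscle myosin gene Myh2 rose by 3.12 (SE 0.584), and by 4.29 without wild-type replicate 2.

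Several of the largest rises differed in size between the cKO libraries. Trim12a was at 25.5 CPM in cKO replicate 1 and 0.274 CPM in cKO replicate 2 against 0.0413 ± 0.0211 CPM in wild type, and its call was lost without either wild-type library (adjusted p = 0.136 without replicate 1 and 0.131 without replicate 2). It was not tested without cKO replicate 1, and it has close paralogs. Nr4a1, an immediate early transcription factor gene, was at 42.5 CPM in cKO replicate 1 and 181.2 CPM in cKO replicate 2 against 6.14 ± 0.118 CPM in wild type. Its log2 fold change of 4.19 (SE 0.677) became 2.80 without cKO replicate 2, and its call held whichever library was left out. The clustered protocadherin genes Pcdhga2, Pcdhgb2 and Pcdhga9, which share their 3' exons, had log2 fold changes of 4.33, 3.30 and 3.87, with SEs of 0.849, 0.868 and 1.212. Pcdhga2 was higher in cKO replicate 1 (59.9 against 13.3 CPM), and the other 2 were higher in cKO replicate 2 (28.9 against 4.32 CPM for Pcdhgb2 and 18.1 against 1.45 CPM for Pcdhga9). Pcdhga2 dropped to 2.87 without cKO replicate 1, Pcdhgb2 to 1.36 and Pcdhga9 to 1.14 without cKO replicate 2. The Pcdhga2 call held whichever library was left out, and that of Pcdhgb2 held without either cKO library. The Pcdhga9 call was lost without cKO replicate 2 (adjusted p = 0.2), and those of Pcdhga9 and Pcdhgb2 were lost without wild-type replicate 1 (adjusted p = 0.0905 and 0.113) or 2 (adjusted p = 0.169 and 0.0812).

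Meiotic genes were lower as groups. Of 12 genes of meiotic entry, 11 fell (11 adjusted over the list alone), 0 rose and 1 did not pass, with a median log2 fold change of -2.06 (camera adjusted p = 4.26e-04; adjusted p = 0.374 with an estimated correlation). Meioc, which is needed to sustain meiotic prophase, fell from 393.1 ± 13.1 to 21.7 ± 5.10 CPM, Dmrtb1 from 383.8 ± 24.0 to 21.9 ± 4.81 CPM and Mael from 1007 ± 260 to 70.4 ± 4.07 CPM. Stra8, named after its values were seen, fell less, from 45.8 ± 23.7 to 20.5 ± 5.94 CPM (log2 fold change -1.16, adjusted p = 0.0377). The entry gene that did not pass was Rec8, which is also in the next list. Among 19 genes of the synaptonemal complex and meiotic cohesin, 16 fell (18 adjusted over the list alone) and the median was -3.41 (camera adjusted p = 2.91e-06; adjusted p = 0.374 with an estimated correlation). The members that did not pass were Rec8 (-0.48), Trip13 (-0.54) and Fkbp6 (-0.34), named after their values were seen. Meikin, a kinetochore regulator of meiosis, fell by 6.96 on the log2 scale (SE 0.313), the central element gene Syce1 by 4.23 (SE 0.198) and the axis gene Hormad1 by 4.0 (SE 0.247). In meiotic recombination, 24 of 28 genes fell (24 adjusted over the list alone), with a median of -2.32 (camera adjusted p = 1.9e-06; adjusted p = 0.374 with an estimated correlation). The symbol Spata22 stands for 2 gene IDs in that list. Cntd1, a crossover regulator gene, fell from 376.8 ± 25 to 4.08 ± 1.05 CPM, Spo11, which makes the meiotic DNA breaks, from 103.2 ± 1.94 to 3.6 ± 0.797 CPM, and Mcmdc2 from 47.8 ± 2.26 to 1.74 ± 0.177 CPM.

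Markers of later germ cells had the lowest medians of the fixed lists. In the list of pachytene and later spermatocytes, 26 of 28 genes fell (26 adjusted over the list alone) and 0 rose, with a median log2 fold change of -5.45 (camera adjusted p = 4.54e-10; adjusted p = 0.374 with an estimated correlation). Spata16, an acrosome gene, fell from 327.6 ± 13.8 to 0.719 ± 0.223 CPM and the sperm surface gene Adam3 from 420.4 ± 12.9 to 1.46 ± 0.610 CPM. Of 25 spermatid genes, 21 fell and 1 rose (21 and 1 adjusted over the list alone), with a median of -5.31, or -4.89 with the 4 members at 0 counts in cKO set to their bounds (camera adjusted p = 1.11e-06; adjusted p = 0.374 with an estimated correlation). Actl7a and Catsper1, which encodes a subunit of the sperm calcium channel, had 0 counts in both cKO libraries and were at least 35.3-fold and 29.7-fold lower. Actl7b fell from 54.2 ± 0.711 to 0.180 ± 0.0559 CPM. The spermatid gene that rose, Spem1, had 0 counts in wild type and 21 in the cKO libraries (0.266 ± 0.0120 CPM). It was not tested without either cKO library. Of 30 listed spermatid genes, 25 were tested, and their wild-type means ran from 0 CPM (Spem1) to 195 CPM (Zpbp2). The germ cells named above for this age are spermatogonia and spermatocytes, so these falls do not show a loss of spermatids.

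Genes of the piRNA pathway, which silences transposons in the germ line, fell in 18 of 20 cases and rose in 1 (19 and 1 adjusted over the list alone), with a median log2 fold change of -2.78 (camera adjusted p = 3.66e-06; adjusted p = 0.374 with an estimated correlation). Piwil1 fell by 6.82 (SE 0.234), the chromatoid body gene Tdrd6 by 7.68 (SE 0.434) and Tdrd12 by 4.20 (SE 0.269). Piwil4, the Piwi gene best known from fetal gonocytes, rose from 3.07 ± 0.637 to 7.98 ± 0.512 CPM. Autosomal retrocopies of X-linked genes, which supply their products when the X chromosome is silenced in meiosis, fell in 9 of 10 cases (9 adjusted over the list alone), with a median of -4.54 (camera adjusted p = 1.1e-04; adjusted p = 0.374 with an estimated correlation). Among them were Pgk2, Prps1l1 (63.1 ± 2.32 to 0.119 ± 0.103 CPM) and Cetn1 (229.3 ± 9.12 to 1.06 ± 0.476 CPM). The Prps1l1 log2 fold change of -9.07 became -10.29 without cKO replicate 2.

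**Figure D2:**
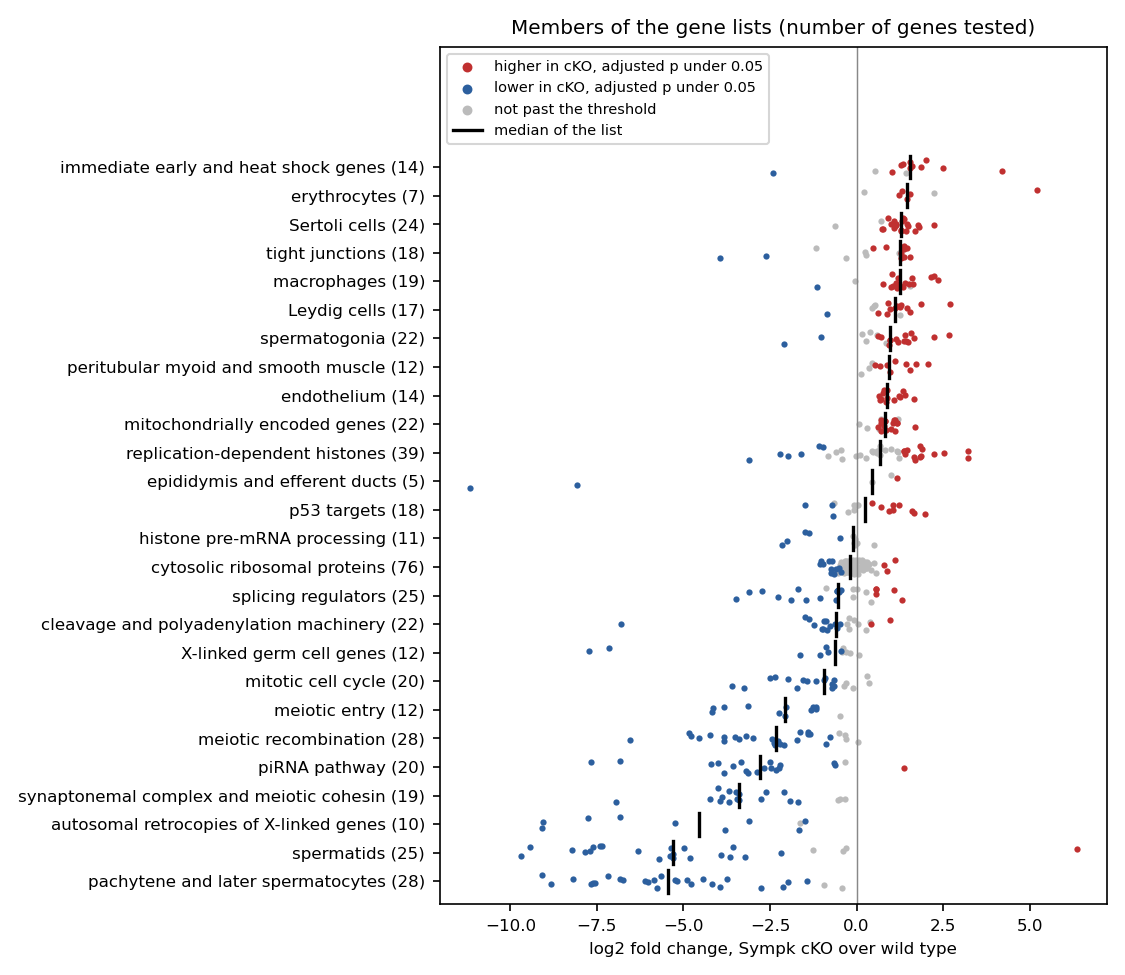
Log2 fold change (Sympk cKO over wild type, x axis) of each tested member of the 26 fixed gene lists, 1 row per list with its number of tested genes. Points are red where higher and blue where lower at adjusted p under 0.05, and grey otherwise. Black lines mark list medians, which ran from -5.45 in pachytene and later spermatocytes to 1.55 in immediate early and heat shock genes on the TMM scale. Relative to the Sertoli list, only erythrocytes and immediate early genes had medians above 0 with all libraries.

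Spermatogonial genes differed from the meiotic ones. Of 22, 15 rose and 2 fell (16 and 2 adjusted over the list alone), with a median log2 fold change of 0.96 that was -0.33 relative to the Sertoli list (camera adjusted p = 8.07e-04; adjusted p = 0.374 with an estimated correlation). Lhx1, a gene of spermatogonial stem cells, was at 0.750 ± 0.0140 CPM in wild type and 4.75 ± 3.07 CPM in cKO. Its log2 fold change of 2.66 (SE 0.516) became 1.78 without cKO replicate 1. Nanos2 and Eomes rose by 2.24 and 1.66 (SE 0.584 and 0.492) from levels under 1 CPM. The Nanos2 call was lost without wild-type replicate 1 (adjusted p = 0.0503), wild-type replicate 2 (adjusted p = 0.096) or cKO replicate 2 (adjusted p = 0.133). The Eomes call was lost without wild-type replicate 1 (adjusted p = 0.0735), wild-type replicate 2 (adjusted p = 0.124) or cKO replicate 1, where its value was 0.92 (adjusted p = 0.178). Id4, which is used as a marker of stem cells but is also expressed in other testis cells, fell from 112.6 ± 0.550 to 26.5 ± 0.0152 CPM.

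Most somatic cell markers were higher in the cKO testes. Of 24 Sertoli cell genes, 22 rose and 0 fell (23 and 0 adjusted over the list alone), with a median log2 fold change of 1.28 (camera adjusted p = 1.9e-06; adjusted p = 0.374 with an estimated correlation). Gdnf, which encodes the growth factor of spermatogonial stem cells, rose from 4.30 ± 0.676 to 20.5 ± 5.99 CPM and Kitl, the ligand of the Kit receptor, from 66.0 ± 8.29 to 230.5 ± 46.8 CPM. Among 17 Leydig cell genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.10, or -0.18 relative to the Sertoli list (camera adjusted p = 9.24e-04; adjusted p = 0.374 with an estimated correlation). Lhcgr, the luteinising hormone receptor gene, rose from 7.78 ± 2.72 to 28.3 ± 3.39 CPM and the steroidogenic gene Cyp17a1 from 56.8 ± 20.7 to 165.5 ± 25.3 CPM. Star, which brings cholesterol into mitochondria, stood at 67.3 and 191.1 CPM in the cKO libraries against 20.01 ± 7.48 CPM in wild type, and its log2 fold change of 2.69 became 1.76 without cKO replicate 2. Ptgds was lower (-0.85, SE 0.304, adjusted p = 0.0479). The call was lost without wild-type replicate 2 (value -0.65), cKO replicate 1 (-1.11) or cKO replicate 2 (-0.63). It was also lost with DESeq2 (adjusted p = 0.0712), limma-voom (adjusted p = 0.0502), a replicate block (adjusted p = 0.0868), library totals alone (adjusted p = 0.111) and no filter on low counts (adjusted p = 0.0539).

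Peritubular, vascular and immune markers followed the same direction. In the list of peritubular myoid and smooth muscle, 9 of 12 genes rose (9 adjusted over the list alone), with a median of 0.93, or -0.35 relative to the Sertoli list (camera adjusted p = 2.21e-03; adjusted p = 0.374 with an estimated correlation). Synpo2 rose by 2.07 (SE 0.270), the intermediate filament gene Des by 1.71 (SE 0.252) and Pdgfrb by 1.55 (SE 0.352), or 2.23 without wild-type replicate 1. All 14 endothelial genes rose (14 adjusted over the list alone), with a median of 0.88, or -0.40 relative to the Sertoli list (camera adjusted p = 2.18e-04; adjusted p = 0.374 with an estimated correlation). Robo4 went from 5.56 ± 1.06 to 17.6 ± 0.944 CPM and the cadherin gene Cdh5 from 34.2 ± 2.34 to 86.6 ± 5.84 CPM. Plvap rose by 1.40 (SE 0.348), a call lost without wild-type replicate 1 (adjusted p = 0.0578) or cKO replicate 1 (adjusted p = 0.0605). Of 19 macrophage genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.25, or -0.03 relative to the Sertoli list and -0.17 to 0.24 with a library left out (camera adjusted p = 1.05e-04; adjusted p = 0.374 with an estimated correlation). The antigen presentation genes Cd74, H2-Aa and H2-Eb1 rose by 2.24, 2.36 and 2.16 (SE 0.203, 0.378 and 0.294), with H2-Aa at 2.96 without wild-type replicate 2, while H2-Ab1, named after its values were seen, did not pass (11.4 ± 2.63 to 10.99 ± 0.147 CPM, adjusted p = 0.837). The Fc receptor gene Fcgr3 fell by 1.15 (SE 0.191). The summed level of 24 skeletal muscle genes, a list chosen after seeing the data, was 185.6 and 1237.4 CPM in the wild-type libraries and 4072.1 and 2532.5 CPM in the cKO libraries beside these rises, and Des is also a skeletal muscle gene.

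Blood and duct markers were sparse. Of 7 erythrocyte genes, 5 rose (5 adjusted over the list alone), with a median of 1.47, or 0.18 above the Sertoli list (camera adjusted p = 0.0265; adjusted p = 0.393 with an estimated correlation). The call was lost without wild-type replicate 1 (adjusted p = 0.0618). The globin genes Hba-a2 and Hbb-bt rose from 3.39 ± 1.06 to 9.86 ± 1.43 CPM and from 21.5 ± 8.06 to 59.3 ± 6.11 CPM. Slc4a1 was at 11.8 and 0.575 CPM in the cKO libraries, and its log2 fold change of 5.22 dropped to 1.79 without cKO replicate 1 (adjusted p = 0.0978). It was also lost without wild-type replicate 1 (adjusted p = 0.126) or 2 (adjusted p = 0.115). Among 5 tested genes of the epididymis and efferent ducts, 1 rose and 2 fell (2 and 2 adjusted over the list alone). The median of 0.44, the mean of -3.33 and the direction of the test (down, camera adjusted p = 0.837; adjusted p = 0.867 with an estimated correlation) did not share a sign, and relative to the Sertoli list the median was -0.84. Without cKO replicate 2 the median was -6.69. Crisp1 and Adam7 had 0 counts in both cKO libraries, at least 98.9-fold and 11.6-fold lower. Crisp1 was at 4.62 and 10.4 CPM in the wild-type libraries, and its bound against wild-type replicate 1 alone was 60.7-fold, while Pax8 rose from 1.35 ± 0.191 to 3.01 ± 0.0720 CPM.

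The machinery in which symplekin acts was moderately lower. Of 22 genes of cleavage and polyadenylation, 13 fell and 2 rose (13 and 2 adjusted over the list alone), with a median log2 fold change of -0.60 (camera adjusted p = 0.0294; adjusted p = 0.374 with an estimated correlation). Papolb, the testis-specific poly(A) polymerase gene, fell from 277.9 ± 11.1 to 2.48 ± 0.903 CPM, and Cstf2t, a testis-enriched retrocopy of Cstf2, from 152.1 ± 0.917 to 54.1 ± 2.13 CPM. Papolg fell by 1.37 (SE 0.140). Pabpn1, the nuclear poly(A)-binding protein gene, rose by 0.96 (SE 0.289), a call lost without cKO replicate 2 (adjusted p = 0.055). The call of the list was lost with library totals alone (median -0.37, adjusted p = 0.073) and without cKO replicate 1 (adjusted p = 0.0548) or 2 (adjusted p = 0.0828).

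Histone genes gave no single direction. Of 39 tested replication-dependent histone genes, whose mRNAs end without a poly(A) tail, 14 rose and 6 fell (14 and 6 adjusted over the list alone), with a median of 0.69, or -0.60 relative to the Sertoli list (camera adjusted p = 0.0242; adjusted p = 0.374 with an estimated correlation). The median turned to -0.93 among members with a mean of at least 5 CPM (adjusted p = 0.426). Hist1h4k had 3 counts in wild type and 32 in cKO, a ratio of 9.9 (exact 95% interval 3.1 to 50.4). Hist1h1d and Hist2h2bb rose by 3.21 and 2.51 from levels under 0.2 CPM. Without wild-type replicate 2 the Hist1h1d value was 4.16, and without cKO replicate 2 the Hist2h2bb value was 1.54. Of these 3 calls, that of Hist1h4k was lost without wild-type replicate 2 (adjusted p = 0.061) or cKO replicate 2 (adjusted p = 0.0734), that of Hist1h1d without wild-type replicate 1 (adjusted p = 0.0634) or cKO replicate 1 (adjusted p = 0.0859), and that of Hist2h2bb without wild-type replicate 1 (adjusted p = 0.0994), wild-type replicate 2 (adjusted p = 0.0721) or cKO replicate 2 (adjusted p = 0.125). Hist3h2bb-ps, a processed pseudogene by annotation, fell by 3.12 (SE 0.387). Among members named after their values were seen, Hist1h1c rose from 10.2 ± 2.01 to 37.3 ± 0.355 CPM. Hist1h2bc, also named so, rose from 11.3 ± 0.886 to 29.4 ± 1.37 CPM. Near-identical copies and the lack of poly(A) tails make the counts of this family uncertain. Of 11 genes that process histone pre-mRNA, 5 fell and 0 rose (5 and 0 adjusted over the list alone), and the list did not pass (median -0.09, or 0.13 with library totals alone, camera adjusted p = 0.192; adjusted p = 0.374 with an estimated correlation). Among them the cap-binding gene Ncbp1 fell from 419.7 ± 1.29 to 94.96 ± 3.97 CPM, Zfp473 from 12.1 ± 1.98 to 2.97 ± 0.530 CPM and the stem-loop binding gene Slbp from 151.1 ± 4.12 to 53.5 ± 4.40 CPM.

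Splicing regulators, tight junctions and p53 targets held changed genes in both directions. Of 25 splicing regulators, 14 fell and 5 rose (14 and 6 adjusted over the list alone), without a call for the list (median -0.54, camera adjusted p = 0.149; adjusted p = 0.374 with an estimated correlation). Khdrbs3 fell from 188.7 ± 18.5 to 16.9 ± 0.0966 CPM, Rbmxl2 by 3.09 (SE 0.212) and Srsf12 by 2.73 (SE 0.405), or -3.46 without cKO replicate 1, while Mbnl1 rose by 1.3 (SE 0.192). Among 18 genes of tight junctions, which build the blood-testis barrier between Sertoli cells, 10 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 1.25, or -0.03 relative to the Sertoli list and -0.34 to 0.01 with a library left out (camera adjusted p = 0.0228; adjusted p = 0.374 with an estimated correlation). Jam2 rose from 73.5 ± 9.18 to 212.0 ± 35.5 CPM and F11r from 76.2 ± 4.99 to 207.1 ± 21.2 CPM. Ybx3, a DNA- and RNA-binding protein gene that is also on the pachytene list, fell from 923.9 ± 3.19 to 60.2 ± 4.37 CPM. Of 18 p53 targets, 9 rose and 3 fell (9 and 3 adjusted over the list alone), and the list did not pass (median 0.25, or -1.03 relative to the Sertoli list, camera adjusted p = 0.149; adjusted p = 0.374 with an estimated correlation). Btg2, the death receptor gene Fas and Eda2r rose by 1.98, 1.65 and 1.6 (SE 0.262, 0.355 and 0.250), and Mdm2, which encodes the ubiquitin ligase of p53, fell from 185.7 ± 4.47 to 66.7 ± 2.13 CPM.

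Genes of the mitotic cell cycle fell in 15 of 20 cases (15 adjusted over the list alone) and rose in 0, with a median of -0.93 (camera adjusted p = 1.99e-03; adjusted p = 0.374 with an estimated correlation). The list also serves meiotic divisions: the kinase gene Aurka fell from 159.2 ± 4.78 to 13.2 ± 2.27 CPM, the cyclin gene Ccnb2 from 112.5 ± 15.7 to 11.7 ± 2.12 CPM and Cdc20 from 197.8 ± 27.0 to 34.9 ± 5.92 CPM.

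Stress-related and mitochondrial transcripts were higher in the cKO libraries. Of 14 immediate early and heat shock genes, which respond within minutes to handling of a tissue as well as to signals, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.55, or 0.27 above the Sertoli list and -0.06 to 0.51 from it with a library left out (camera adjusted p = 9.36e-04; adjusted p = 0.374 with an estimated correlation). Besides Nr4a1, Atf3 rose by 2.51 (SE 0.409), or 3.13 without wild-type replicate 2, and Junb by 2.0 (SE 0.350), or 1.41 without cKO replicate 2. Dnajb1, a co-chaperone gene, fell from 192.7 ± 11.6 to 36.5 ± 1.34 CPM. Of 22 mitochondrially encoded genes, 16 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.81, or -0.47 relative to the Sertoli list and -0.64 to 0.01 with a library left out (camera adjusted p = 1.77e-04; adjusted p = 0.374 with an estimated correlation). The complex I genes mt-Nd5 and mt-Nd2 went from 4017 ± 1215 to 9045 ± 935 CPM and from 1783 ± 471 to 3983 ± 705 CPM. The transfer RNA gene mt-Tk, with 7 counts in wild type and 25 in cKO, passed with all libraries (adjusted p = 0.0352) but lost the call whichever library was left out (adjusted p = 0.129 to 0.228). The summed skeletal muscle level given above was also higher in both cKO libraries, but the groups did not order the libraries alike within the genotypes. Summed mitochondrial levels were 54220.6 and 42622.3 CPM in wild-type replicates 1 and 2, and 97588.6 and 79023.8 CPM in cKO replicates 1 and 2. Summed immediate early and heat shock levels were 307.6 and 314.6 CPM in wild type, and 356.6 and 553.6 CPM in cKO, in the same order. Genes of cytosolic ribosomal proteins fell in 11 of 76 cases and rose in 3 (0 and 0 adjusted over the list alone), and the list did not pass (median -0.19, or 0.03 with library totals alone, camera adjusted p = 0.468; adjusted p = 0.867 with an estimated correlation). Without wild-type replicate 1 it passed (median -0.25, adjusted p = 0.027). Rpl36 fell by 1.06 (SE 0.188). Rps25 and Rpl30 were lower by -1.02 and -0.98, calls lost without cKO replicate 2 (adjusted p = 0.0778 and 0.0742) and with library totals alone (adjusted p = 0.058 and 0.0541), while X-linked Rps4x rose by 1.11 (SE 0.221).

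Of the 26 lists, camera with the preset correlation called 21. With an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05 (spermatids, p = 0.0306), while fry called 24. The marker lists of cell types also hold genes that several cell types of the testis express.

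Genes of the X chromosome were more often higher than those of the autosomes. Sex chromosome genes are silenced in pachytene spermatocytes, so the comparison asks whether X-linked transcripts follow the germ cell stages. Of 922 X-linked genes tested, 436 were higher (47.3%) and 155 lower (16.8%), with a median log2 fold change of 0.62. Of 20831 autosomal genes, 5906 were higher (28.4%) and 7306 lower (35.1%), with a median of -0.05. Among protein-coding genes, 56.5% on the X chromosome and 32.6% on autosomes were higher, with medians of 0.81 and 0.07. Of 32 Y-linked genes, 5 were higher (15.6%) and 9 lower (28.1%), with a median of -0.12. X-linked genes as a set were higher than the other genes by camera with the preset correlation (p = 2.9e-05) but did not pass by camera with an estimated one (p = 0.0585), and fry, which sets them against no change and not against other genes, gave p = 0.00993. Scaling to the Sertoli list, which moves every gene alike, turns the X-linked median below 0 and leaves its distance to the autosomes. By contrast, of 12 X-linked germ cell genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.63 (camera adjusted p = 0.0228; adjusted p = 0.374 with an estimated correlation). Slxl1 and Tex13a had 0 counts in both cKO libraries, at least 9.1-fold and 6.1-fold lower, and Tex16 fell from 40.5 ± 3.29 to 13.1 ± 2.74 CPM. The call of this list was lost among genes with a mean of at least 5 CPM (median -0.39, adjusted p = 0.107).

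**Figure D3:**
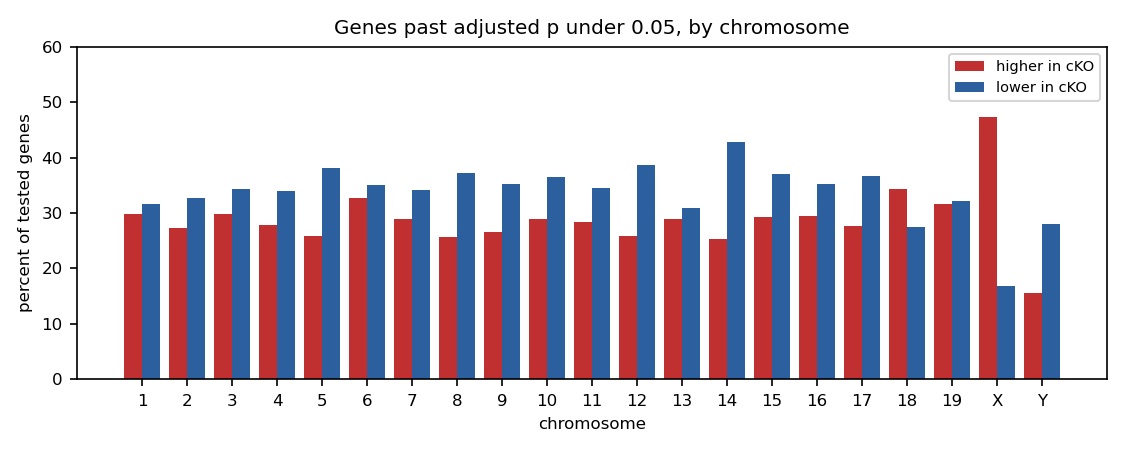
Percent of tested genes on each chromosome (x axis) that were higher (red) or lower (blue) in Sympk cKO at adjusted p under 0.05, on the TMM scale. On the X chromosome 47.3% were higher and 16.8% lower, while on autosomes the share of higher genes ran from 25.4% (chromosome 14) to 34.3% (chromosome 18).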

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

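Of 1203 values of named genes under the alternatives, 1152 kept direction and side of the threshold, 51 kept direction and lost the call, and 0 reversed; of 285 list values, 270 were the same, 6 lost and 1 gained the call, and 8 reversed. Scaling to the Sertoli list was chosen after seeing the data. With a mean of at least 5 CPM, 9228 genes changed, 4620 of them lower, and 5772 at least 2-fold, with 13299 genes tested, and the histone list median turned to -0.927. Scaled to the Sertoli list, 392 genes were higher and 13524 lower; 7869 calls were shared in direction with the TMM scale. Taking the muscle, immediate early and mitochondrial genes out of the finished results, also chosen after seeing the data, left 6330 higher and 7475 lower. Only the p-value adjustment was repeated, not the scaling or the fit, so this does not test whether those genes affect the others. Library totals alone turned the medians of histone pre-mRNA processing (0.127) and of ribosomal proteins (0.033). The epididymis median was -4.724 with DESeq2, -3.382 without a filter, and -6.687 to 0.108 with a library left out; the cause was not tested. An estimated correlation left 0 lists called. Sympk ranged from -0.406 to -0.161 with a library left out. The replicate numbers share only a number: same-numbered libraries had a deviation correlation of -0.07, and a replicate block gave 5632 higher and 6937 lower genes, lost 3 of 112 gene calls (Pcdhga9, Ptgds, mt-Tk) and the cleavage and polyadenylation list (adjusted p = 0.0515). With RLE size factors and limma-voom, all 26 lists kept their direction and side of the threshold. Of 112 gene calls, limma-voom lost 5 (Trim12a, Pcdhga9, Pcdhgb2, Ptgds and Slc4a1), DESeq2 lost 3 (Nanos2, Ptgds and mt-Tk) and RLE size factors lost 0. A gene under 0.072 to 0.092 CPM lies below the floor of a library, so small or low changes can be missed. Simulated data recovered 42.4% of 2-fold changes, but with 200 changed genes, so the share missed in these data is not known. The pseudocount alternative was not run, since the values are counts.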

Other observations

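The gene lists in this part, and all tests except those of the shares of overlapping genes and of upstream genes, were chosen after the results were seen. Genes of the sperm tail's axoneme fell together and deeply. Of 70 tested genes for axonemal dyneins, tektins, radial spoke and cilia- and flagella-associated proteins, 63 fell and 0 rose, with a median log2 fold change of -5.25 (camera adjusted p = 1.73e-17; adjusted p = 0.653 with an estimated correlation). Tekt3 fell from 87.1 ± 5.02 to 0.151 ± 0.213 CPM, the radial spoke gene Rsph6a from 144.0 ± 21.3 to 0.287 ± 0.175 CPM and the central pair gene Spag17 from 483.8 ± 96.2 to 1.87 ± 0.424 CPM (SD, n = 2). Of 38 proteasome subunit genes, 20 fell and 5 rose (median -0.53, camera adjusted p = 0.0327; adjusted p = 0.653 with an estimated correlation), and the call was lost without cKO replicate 1 (adjusted p = 0.0786) or 2 (adjusted p = 0.129). Among members named after their values were seen, Psma8, the subunit of the spermatocyte proteasome, fell from 468.3 ± 49.0 to 11.9 ± 1.99 CPM, while the immunoproteasome genes Psmb8, Psmb9 and Psmb10 rose by 1.2, 1.24 and 1.03 (SE 0.273, 0.284 and 0.213), less than the Sertoli list. Nuclear genes of mitochondrial complex I fell in 25 of 36 cases and rose in 2 (median -0.81, camera adjusted p = 1.07e-03; adjusted p = 0.653 with an estimated correlation), opposite to the mitochondrially encoded ones; Ndufv2 fell from 140.4 ± 21.1 to 41.5 ± 4.99 CPM.

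Matrix genes rose with the somatic markers. Of 43 collagen genes, 33 rose and 4 fell (median 1.33, or 0.05 from the Sertoli list, which became 0.5 without wild-type replicate 1 and -0.28 without wild-type replicate 2, camera adjusted p = 1.21e-05; adjusted p = 0.653 with an estimated correlation). Col1a1 rose from 405.8 ± 123 to 1121 ± 27.9 CPM and the basement membrane gene Col4a1 from 311.5 ± 84.1 to 842.5 ± 54.6 CPM, while the cartilage collagen gene Col2a1 fell from 27.7 ± 9.33 to 2.67 ± 0.995 CPM. Of 28 genes of the Adamts and Mmp proteases, 19 rose and 2 fell (median 1.22, or -0.06 relative to the Sertoli list, 0.35 without wild-type replicate 1 and -0.26 without wild-type replicate 2, camera adjusted p = 2.73e-04; adjusted p = 0.653 with an estimated correlation), among them Mmp2 (28.2 ± 7.07 to 78.7 ± 6.15 CPM). Of 8 Y-linked genes, 3 rose, 2 fell and 3 did not pass. The broadly expressed Ddx3y, Kdm5d and Uty rose by 1.22, 1.31 and 1.09 (SE 0.145, 0.145 and 0.152), while the germ cell genes Zfy1 and Zfy2 fell by 1.47 and 1.29 (SE 0.347 and 0.279). Eif2s3y, Usp9y and Uba1y did not pass. The list as a whole did not pass (median -0.03, or -1.31 relative to the Sertoli list, camera adjusted p = 0.554; adjusted p = 0.653 with an estimated correlation). By annotation class, 577 of 1061 long intergenic RNA genes were lower and 195 higher (median -1.82), and 377 of 727 antisense genes were lower and 110 higher (median -1.25), against 5368 lower and 5562 higher of 16525 protein-coding genes (median 0.10). Antisense counts are uncertain here, since the strand setting is not given in the sources used here.

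The marker lists of Sertoli, Leydig, peritubular, endothelial and macrophage cells and of spermatogonia had medians above 0 in the cKO testes, on the TMM scale. Id4, Sohlh2, Ptgds and Fcgr3 fell, though the Ptgds call was lost under several alternatives. More interstitial tissue taken with the cKO testes would leave Sertoli cells, which sit inside the tubules, at or below 0. The Sertoli median was 1.28 on the TMM scale (95% bootstrap interval over genes 1.1 to 1.38). Scaling to the Sertoli list takes out the mean rise of that list, so the sign of this median cannot decide. Relative to the Sertoli list, the Leydig, endothelial and macrophage medians were -0.18, -0.40 and -0.03. No excess of these interstitial markers was thus seen with all libraries, although the macrophage value reached 0.24 with a library left out. A lower share of RNA from spermatocytes would raise the other cell types alike. The medians of the 6 lists spanned 0.4 on the log2 scale, no more than genes shuffled among the lists gave (permutation p = 0.398). The shuffling treats genes as replicates, and genes within a list differed widely, so modest differences between lists could be missed. Any cause that moves the 6 lists alike, the scaling included, would pass as well. A lower share of spermatocyte RNA is thus possible, but the test does not decide for it. The listed pachytene transcripts themselves did take a lower share of the counts, with 26 of 28 lower and a median of -5.45. Whole-testis counts do not separate fewer spermatocytes from less of these transcripts in each. A change of gene activity inside Sertoli cells or spermatogonia stays open and was not tested.

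Skeletal muscle genes were higher in the cKO libraries and differed within wild type. Of 24, 11 rose and 1 fell, the glycolytic gene Eno3 (median 2.53, camera adjusted p = 7.7e-04; adjusted p = 0.653 with an estimated correlation; fry p = 0.138). Their median exceeded that of the Sertoli list by 1.24 (95% bootstrap interval over genes 0.93 to 1.49). The excess stayed above 0 whichever library was left out, at 0.54 (0.16 to 0.76) without wild-type replicate 1, 3.4 (2.49 to 5.9) without wild-type replicate 2, 0.91 without cKO replicate 1 and 1.54 without cKO replicate 2. Between single libraries, cKO replicates 1 and 2 exceeded wild-type replicate 1 by 3.6 (2.7 to 5.96) and 2.97 (2.15 to 5.64) and wild-type replicate 2 by 0.69 (0.41 to 0.98) and 0.09 (-0.18 to 0.39), so the size of the excess is uncertain. A lower share of spermatocyte RNA would move muscle and Sertoli genes alike, which was not seen with all libraries. Within wild type, however, replicate 2 exceeded replicate 1 by 3.13 (1.88 to 5.24), more than the 1.24 between genotypes. The intervals treat genes as replicates and leave out the spread between samples. An excess tied to genotype is therefore not shown, and these values do not decide how far a lower spermatocyte share contributed. Between the wild-type libraries the muscle genes differed together: 95.8% of them (23 of 24) lay on one side, with Acta1 at 0.211 and 82.3 CPM and Ckm at 0.132 and 65.6 CPM in wild-type replicates 1 and 2, and at 288.5 and 169.5 CPM and 217.6 and 116.0 CPM in cKO replicates 1 and 2. Of the 24, 7 were at 5 CPM or more in wild-type replicate 1, so part of the list may also be expressed in testis, and 0 are in another list. Muscle taken along in dissection, in differing amounts, may therefore account for these genes, Myh2 among them. A genotype effect on the muscle beside the testis was not tested.

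A set of 21 genes lay under 3 CPM in wild type and was at least 8-fold higher in the cKO libraries, with both cKO libraries within 2-fold of each other and a mean of at least 1 CPM; Kctd12, Clmn, Frrs1, Wipf1 and Pet117 are among them. Reads of an overlapping gene could raise such counts: 42.9% of the set overlapped another tested gene against 33.9% of all tested genes (Fisher's exact test, two-sided, p = 0.489). Transcription that runs on past the end of an upstream gene, a candidate explanation given the role of symplekin in 3' end formation, would place an expressed gene of the same strand within 10 kb upstream, and 4.8% of the set (1 of 21, exact 95% interval 0.1% to 23.8%) had one against 14.6% of all (Fisher's exact test, p = 0.349). A chromosome segment carried along with the modified allele would place the set near Sympk, and 9.5% (2 of 21, Rnf225 and Gm44617) lay within 20 Mb of it against 2.7% (Fisher's exact test, p = 0.108). With 21 genes, none of these shares could be told from its background. By position, an overlap with a tested gene cannot account for the 12 members that overlap none. Nor can a segment within 20 Mb of Sympk account for the 19 outside it. For the other 9 and 2 members these explanations stay open. An upstream gene counted only if it was tested, on the same strand, at a mean of at least 5 CPM and not overlapping the member. Run-on from weaker, overlapping or opposite-strand genes was therefore missed, and the strand setting is not given. Run-on within 10 kb thus stays open for all 21, including the 20 without such an upstream gene. Run-on over longer distances and a direct effect of the knockout were not tested.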
